A study of Malus domestica with 12 samples.

How the data were processed

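RNA was measured in 12 libraries from roots of the apple rootstock M9T337 (Malus domestica), 3 in each of 4 groups. Total RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and marks the strand, per the labels' protocols. Trimmomatic and HISAT2 are named in the submitters' processing notes, without versions. The genome build, the gene annotation and the tool that counted reads are not given in the sources used here, nor is the use of strand in counting, so genes that overlap or share reads with near-identical copies are uncertain. The authors deposited FPKM, fragments per kilobase of gene scaled to a library total, for 46558 genes in each library, with no replicates pooled. Each library was assigned to its group by its label, and 0 columns were left unmapped.

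FPKM values are not counts, and they were tested on a log scale. Reads in genes were worked out from the values themselves. Within a gene and a library, 1 read is worth a fixed FPKM step set by the gene's length and the library's total, so the lengths and totals that turn every value of a gene into whole reads could be found. All 37961 genes with a value above 0 in at least 3 libraries had such a length, and 100% of their values lay within 0.05 of a whole read. These genes held at least 99.993% of each library's total. The totals therefore count reads assigned to genes, and give neither the sequencing depth nor the share of reads mapped. Library totals obtained in this way ranged from 16975829 to 18108121 reads. At the median gene length of 1484 bp, 1 read was worth between 0.0372 and 0.0397 FPKM. The lengths are those the authors' counting implies and were not compared with an annotation. On simulated tables with known reads, every read count was recovered exactly for 99.99% of 29537 tested genes.

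The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested, 30459 in all. One fit with a coefficient per group left 8 residual degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and the number that also changed at least 2-fold is given beside it. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The 6 contrasts were Ta against CK, Fp against CK, TaFp against Fp, TaFp against Ta, TaFp against CK and the interaction, which is TaFp minus Fp less Ta minus CK. Correlations of fold changes are Pearson's r across genes, and genes are not independent replicates. For Ta and Fp, which share the CK libraries, r and the covariance were set beside those of 100 simulated draws of unchanged groups, and r was computed again with the controls split.

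Gene identifiers were used as the files give them. The files do not pair them with names or descriptions, and 0 of them matched an identifier in the supplied gene table of the RefSeq assembly GDT2T_hap1. The 44 lists of genes fixed on product descriptions before the data were examined were therefore not run, and no gene names or functions are given. The rule for named genes, fixed at the same time, then took from each contrast the 2 genes with the largest rise and the 2 with the largest fall among those called, and for comparisons of 2 groups only genes whose 3 libraries of one group all lay on one side of the other 3. The digits after MD were read as the chromosome, by the naming convention of apple gene models, with 00 for unplaced genes, and the serial number as the order along it. Read ratios of named genes carry exact binomial 95% intervals on the summed reads, which cover the counting error of independent reads only. The spread between replicates was larger than that, so these intervals are too narrow.

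Groups of genes were formed from the calls of at least 2-fold, chromosome shares were tested with two-sided Fisher's exact tests adjusted over 180 tests, and neighbouring tested genes were compared with 100 permutations of the calls within each chromosome. The alternatives were other pseudocounts (0.1 and 0.5), no filter, a mean FPKM of at least 5, TPM rescaling, median centring, quantile normalization, no variance trend, a robust variance, a stricter adjusted p of 0.01, a replicate block, fits to only the libraries compared, and leaving out each library. Chosen after seeing the data were a gene length trend removed from each library (natural spline, 5 degrees of freedom), limma voom on the recovered reads, the split controls and leaving out the 100 genes with the most reads. For the correlations and the counts of at least 2-fold, leaving out each library was also added then. Also chosen then were counting the groups of genes again under other settings and taking the group means of named genes without each library. The interaction was also tested on 100 tables, the real one and others with the residuals of an additive fit permuted over libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the reads and figures.

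The fit was tested on simulated data for Ta against CK, with 50 planted changes of each size among 29154 tested genes. It recovered 6% of planted 1.2-fold changes, 68% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes, with 7 false calls and 0 wrong signs. A planted length trend, beside 200 genes with planted changes, gave 5707 calls among 29291 genes, and 146 after its removal. After removal, 100% of planted 4-fold changes were still called.

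Rescaling the FPKM to TPM moved the median log2 fold change of all tested genes from -0.017 to -0.122 for Ta against CK, from -0.085 to -0.244 for Fp against CK, from 0.113 to 0.238 for TaFp against Fp, and from 0.152 to 0.384 for the interaction. Quantile normalization and removal of the length trend moved it the other way for TaFp against Fp, to -0.041 and -0.059, and for the interaction, to -0.078 and -0.112. With each library centred on its median, the genes changed at least 2-fold numbered 4892, 6412, 4575, 5605, 3760 and 11732 in the order of the contrasts above. Directions of single genes are therefore relative to the library scaling, and counts of higher and lower genes are given with other scalings where the split moved by more than 10 percentage points.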

Results

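Gene expression was measured in roots of M9T337, a dwarfing apple rootstock, after inoculation with 2 fungal strains known in the labels as 6S-2 and MR5. As background, 6S-2 is a strain of Trichoderma asperellum, a root-colonising fungus, and MR5 is a strain of Fusarium proliferatum, a root pathogen. Control roots (CK) were inoculated with PDB medium. Roots of the group Ta received a spore suspension of 6S-2 alone, roots of Fp received PDB medium and then MR5, and roots of TaFp received 6S-2 and then MR5. The labels name a second inoculation only for Fp and TaFp, so changes with MR5 cannot be told apart from those of that step. Each group had 3 libraries. The labels do not say that these came from separate plants, so the p-values measure the spread between these samples, which may be technical.

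Library totals of reads in genes were close. The recovered reads per library ranged from 17311640 to 17589179 in CK, from 17723365 to 17849891 in Ta, from 16975829 to 17463961 in Fp and from 18039628 to 18108121 in TaFp. The number of genes at 1 FPKM or more was highest in TaFp, at 29029 ± 36.7, followed by 28072 ± 8.08 in CK, 27374 ± 143 in Fp and 27179 ± 64.2 in Ta (SD, n = 3 each). The values of TaFp and those of each other group did not overlap, and 0.1 is the smallest two-sided exact permutation p that 3 libraries against 3 can give. For genes with at least 200 reads, the median coefficient of variation between the 3 libraries of a group was 4.55% in TaFp, 5.24% in Ta, 5.48% in CK and 5.53% in Fp. With the counting noise of independent reads taken off, 2.06%, 3.18%, 3.57% and 3.58% were left in that order. The median variance of 3 libraries lies below the expected one and reads may not be independent. These remainders and their order are therefore uncertain. All pairs of libraries in a group differed by more than the counting noise of independent reads. Such noise gives a mean chi-square per gene of about 1. In the bin of genes with the fewest reads it was 1.81 to 2.34, so part of the excess may come from reads that are not independent. In the bin with the most reads it was 3.17 to 15.8. No library was therefore treated as a repeat of another, although such a spread can also arise between libraries of 1 RNA sample.

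All 12 libraries correlated best with a library of their own group across genes. Within groups r lay between 0.989 and 0.992. Between groups the closest were Ta and Fp, at 0.945 to 0.951, and the farthest were CK and Fp, at 0.837 to 0.847. CK and TaFp reached 0.885 to 0.89, which overlapped Fp and TaFp at 0.879 to 0.887. CK and Ta lay at 0.872 to 0.879, and Ta and TaFp at 0.853 to 0.858. The first principal component held 53% of the variance and placed CK and TaFp on one side and Ta and Fp on the other. The second held 30.7% and ran from CK through Ta and Fp to TaFp.

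**Figure D1:**
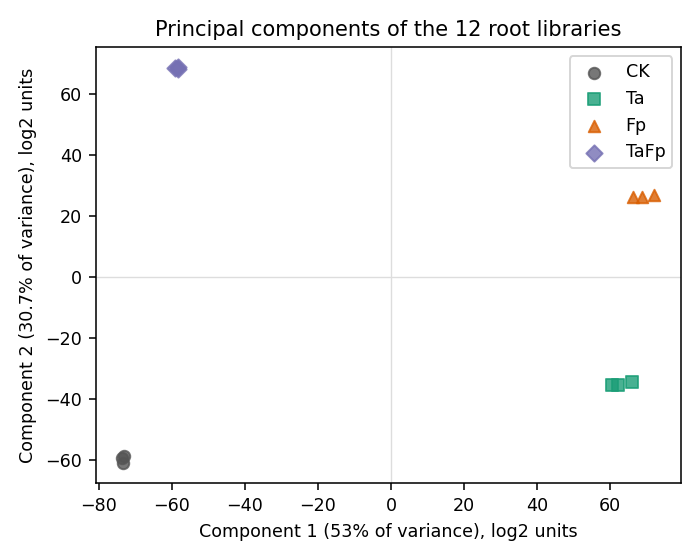
Principal components 1 and 2 of log2(FPKM + 1) over 30459 genes, with 1 point for each of the 12 libraries and a marker for each group. The 3 libraries of each group lie together, and CK and TaFp lie at negative values of component 1, with Ta and Fp at positive values.

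The first comparison asks what 6S-2 alone changed in roots. Among genes that changed strongly against CK, more were lower than higher, with 1806 genes at least 2-fold higher and 3114 at least 2-fold lower. MD09G1256000 rose from 7.02 ± 1.4 FPKM in CK to 774 ± 18 in Ta (SD, n = 3 each), and MD10G1022900 rose from 0.791 ± 0.25 to 142 ± 6 FPKM. MD05G1255500 fell from 299 ± 36 to 0.594 ± 0.17 FPKM, and MD15G1255700 fell from 148 ± 2.6 to 0.318 ± 0.11 FPKM. In 41 genes every CK library held at least 100 reads and every Ta library at most 3, and the opposite held for 5 genes.

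These 4 genes changed by 6.61, 6.33, -7.55 and -6.82 on the log2 scale, with standard errors of 0.087, 0.093, 0.111 and 0.095 and limma adjusted p of 2.67e-16, 7.27e-16, 7.27e-16 and 4.06e-16. Of 30459 tested genes, 20088 changed at an adjusted p under 0.05, with 9529 higher and 10559 lower. The larger side of this split turned with other settings, to 10916 higher and 9388 lower after quantile normalization, to 11170 and 8599 with the gene length trend removed and to 7431 and 7098 at a mean FPKM of at least 5. On chromosome 13, 8.1% of 1693 tested genes were at least 2-fold higher against 5.9% of all tested genes, the 1 of 180 chromosome tests that passed (Fisher's exact test, adjusted p = 0.0365). That test takes genes as independent, while 795 neighbouring pairs shared a call in this comparison against a mean of 425 in permutations, so its p is too small. The reads of Ta came from shorter genes, with a read-weighted mean length of 1952 ± 23.6 bp against 2161 ± 8.5 bp in CK (SD, n = 3 each).

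The second comparison asks what MR5 alone changed. Fp had the largest number of strongly changed genes among the 3 treatments set against CK, with 2744 genes at least 2-fold higher and 3722 at least 2-fold lower. MD10G1022900, already named for 6S-2, rose to 214 ± 4.5 FPKM (SD, n = 3). MD15G1176400 rose from 0.207 ± 0.07 to 144 ± 10 FPKM. MD14G1158400 fell from 334 ± 4.6 to 3.08 ± 0.37 FPKM, and MD05G1255500 fell to 2.78 ± 0.53 FPKM.

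The log2 fold changes of these 4 genes were 6.92, 6.91, -6.37 and -6.31, with limma adjusted p of 2.37e-16, 1.46e-16, 1.75e-17 and 3.46e-15. MD15G1176400 held only 9 reads over the CK libraries and 6178 over the Fp libraries, a ratio of 697 (95% interval 367 to 1530). In all, 22146 genes changed, 9713 higher and 12433 lower. The share of higher genes among those changed at least 2-fold was 42.4%, and 31.3% after TPM rescaling, 50.3% after median centring, 48.4% after quantile normalization and 47.4% with the length trend removed. Over all changed genes it was 43.9%, and median centring turned the split, to 11062 higher and 10952 lower, as did removal of the length trend, to 10859 and 10504. A run of 9 neighbouring tested genes on chromosome 13, from MD13G1160500 to MD13G1161400, was at least 2-fold higher throughout, by 1.37 to 4.55 on the log2 scale; this run was singled out after its values were seen. The read-weighted mean gene length in Fp was 1846 ± 21.2 bp (SD, n = 3), below that of every CK library.

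The changes with 6S-2 alone and MR5 alone resembled each other. Of the genes at least 2-fold higher, 1347 were higher in both Ta and Fp, where independent lists would share 163. Of those at least 2-fold lower, 2210 were lower in both, against 381 for independent lists. The main fit's 1347 became 2029 with a pseudocount of 0.1 and 2097 with voom on recovered reads, and its 2210 became 1278 at a mean FPKM of at least 5. Opposite changes were seen in 9 and 12 genes, where independent lists would give 221 and 281. The 21 genes with opposite changes in the main fit became 88 with voom on recovered reads and 33 with TPM rescaling. Their number was 22 with the length trend removed and 20 after quantile normalization. MD09G1256000, MD10G1022900 and MD13G1208400 rose in both Ta and Fp, and MD05G1255500, MD15G1255700 and MD14G1158400 fell in both.

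Across genes, the log2 fold changes of Ta and of Fp against CK had r = 0.827 and a covariance of 0.6677. Unchanged groups simulated against shared controls gave r = 0.499 and a covariance of 0.0093, a difference in covariance of 0.6584. With the controls split so that no CK library was shared, r lay between 0.798 and 0.809.

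The third comparison asks what 6S-2 before MR5 changed relative to MR5 alone. Most strongly changed genes were higher in TaFp than in Fp, with 3385 at least 2-fold higher and 1450 at least 2-fold lower. MD04G1031500 rose from 1.23 ± 0.81 FPKM in Fp to 188 ± 1.3 in TaFp (SD, n = 3 each), and its neighbour by identifier, MD04G1031400, rose from 5.12 ± 1.9 to 249 ± 4.3 FPKM. The sequences of these neighbours were not compared here, so reads shared between them are not excluded. MD09G1256000 fell from 953 ± 28 to 9.17 ± 0.69 FPKM, and MD13G1208400 fell from 407 ± 2.2 to 3.66 ± 0.79 FPKM. Of the run of 9 genes on chromosome 13 that were higher in Fp, 7 neighbours, from MD13G1160700 to MD13G1161400, were at least 2-fold lower in TaFp than in Fp.

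The named genes changed by 6.48, 5.41, -6.55 and -6.47 on the log2 scale with limma adjusted p of 5.23e-12, 5.37e-12, 3.56e-16 and 1.47e-15. In all, 20627 genes changed, 12371 higher and 8256 lower. The share of higher genes depended on the scaling: it was 60% in the main fit, 47.7% after quantile normalization and 44.2% with the gene length trend removed. Among genes changed at least 2-fold it was 70% in the main fit and 57.6% after quantile normalization.

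The change with 6S-2 ran largely in opposite directions with and without MR5. Of genes at least 2-fold lower with 6S-2 alone, 1483 were at least 2-fold higher in TaFp than in Fp, against 346 for independent lists. Of genes at least 2-fold higher with 6S-2 alone, 781 were lower in TaFp than in Fp, against 86. Changes in the same direction were fewer than independent lists would give, with 42 genes higher in both against 201 and 51 lower in both against 148. The log2 fold changes of these comparisons, which share no library, had r = -0.632 across genes. This result is not separate from the likeness of Ta and Fp. A gene changed alike in both and less in TaFp gives opposite signs here. Against CK, most genes changed in both kept their direction in TaFp. At any size, 938 of the 1347 higher genes were called higher in TaFp and 148 lower. Of the 2210 lower genes, 1441 were called lower and 207 higher.

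The fourth comparison sets TaFp against Ta and asks what MR5 changed in roots already treated with 6S-2. Higher genes again dominated the strong changes, with 4154 at least 2-fold higher and 1544 at least 2-fold lower. MD11G1238600 reached 199 ± 5 FPKM in TaFp, where the 3 Ta libraries held 1 to 2 reads each, and MD04G1031500 rose from 1.34 ± 0.52 to 188 ± 1.3 FPKM (SD, n = 3 each). MD09G1256000 fell from 774 ± 18 to 9.17 ± 0.69 FPKM, and MD09G1256300 fell from 222 ± 12 to 2.57 ± 0.37 FPKM. The identifiers of these falling genes are close, and both genes were high in Ta and Fp and low in CK and TaFp. Their sequences were not compared, so reads shared between them are not excluded.

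MD11G1238600 had 14218 reads over TaFp and 4 over Ta, a ratio of 3500 (95% interval 1370 to 12900), with a limma adjusted p of 8.03e-14. The other named genes changed by 6.36, -6.25 and -5.97 on the log2 scale, with adjusted p of 4.13e-12, 5.44e-16 and 2.01e-16. In all, 20989 genes changed, 11284 higher and 9705 lower. The share of higher genes was 53.8%, and it was 43.3% after quantile normalization, 40.6% with the length trend removed and 46.5% at a mean FPKM of at least 5. Among genes changed at least 2-fold it was 72.9% and, after quantile normalization, 60.6%. The changes with MR5 in roots with and without 6S-2 had r = -0.291 across genes, which is again not separate from the likeness of Ta and Fp. At least 2-fold, 1303 genes were lower with MR5 alone and higher in TaFp than in Ta, against 508 for independent lists, and 631 were higher with MR5 alone and lower in TaFp than in Ta, against 139. In the same direction, 518 were higher in both, against 374, and 129 were lower in both, against 189.

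The fifth comparison sets TaFp against CK. Roots that received both strains had the fewest strongly changed genes of the 3 treatments, with 2496 at least 2-fold higher and 1285 at least 2-fold lower. MD11G1238600 rose from 0.948 ± 0.74 to 199 ± 5 FPKM and MD02G1023200 from 0.356 ± 0.16 to 115 ± 4.5 FPKM (SD, n = 3 each). The CK mean of MD11G1238600 depends on 1 library, with 1.8 FPKM from 41 reads, and is 0.521 FPKM without it. The log2 fold change is then 7.04, against 6.75 with all libraries. MD07G1278100 fell from 111 ± 5.4 to 0.445 ± 0.18 FPKM, and MD03G1011800 fell from 145 ± 7.4 to 2.95 ± 0.6 FPKM. MD07G1278100 was also low with either strain alone, at 0.729 ± 0.36 FPKM in Ta and 1.52 ± 0.12 in Fp.

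Their log2 fold changes were 6.75, 6.42, -6.28 and -5.22, with limma adjusted p of 4.24e-13, 8.62e-16, 5.82e-14 and 4.46e-14. In all, 17578 genes changed, 9017 higher and 8561 lower. This split turned to 8222 higher and 10113 lower after quantile normalization, to 7926 and 10195 with the length trend removed, to 8418 and 9320 after TPM rescaling, to 8824 and 8830 after median centring and to 5924 and 6718 at a mean FPKM of at least 5. The read-weighted mean gene length of TaFp was 2106 ± 6.66 bp (SD, n = 3), nearer to CK than that of Ta or Fp.

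**Figure D2:**
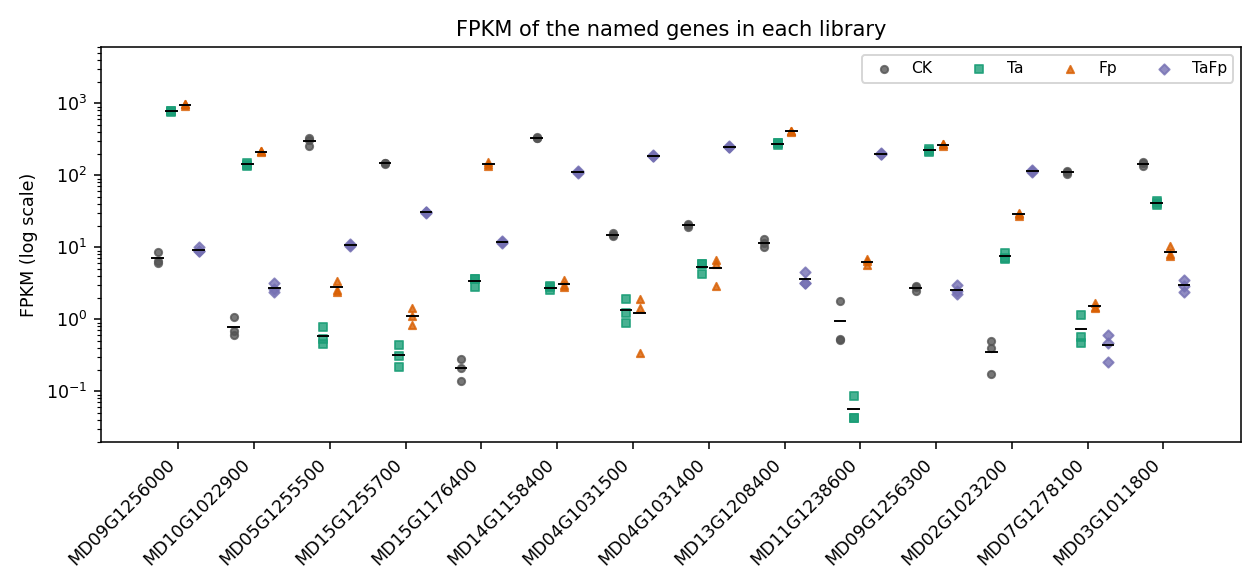
FPKM of the 14 named genes on a log axis, with 1 point for each library, a marker for each group and a line at each group's mean. MD09G1256000 lies at 774 and 953 FPKM in Ta and Fp and at 7.02 and 9.17 in CK and TaFp, while MD04G1031500 lies at 188 FPKM in TaFp and at 14.9 or less in the other groups.

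Genes were then followed across all groups. Of the 1347 genes at least 2-fold higher in both Ta and Fp, 440 were at least 2-fold higher in TaFp than in CK, 29 were at least 2-fold lower and the others were not called at that size. At any size, 938 of the 1347 were called higher in TaFp than in CK and 148 lower. Of all tested genes, 8.2% were at least 2-fold higher in TaFp than in CK and 4.2% at least 2-fold lower. Against Fp, 697 of the 1347 were at least 2-fold lower in TaFp and 35 at least 2-fold higher. These numbers depend on the settings. With a pseudocount of 0.1 the class held 2029 genes, of which 902 were higher in TaFp than in CK, 61 lower, and 122 higher than in Fp. With voom it held 2097, with 938, 61 and 131. With a pseudocount of 0.5 it held 1610, with 584, 39 and 57. The share higher in TaFp than in CK was 32.7% in the main fit and 44.7% with voom, and the share lower than in Fp was 51.7% and 45.4%. In the main fit the median log2 fold change of the 1347 against CK was 1.46 in Ta, 1.73 in Fp and 0.58 in TaFp. Of the 2210 genes at least 2-fold lower in both, 665 were at least 2-fold lower in TaFp and 48 at least 2-fold higher, with medians of -1.67, -1.68 and -0.57. At any size, 1441 of the 2210 were called lower in TaFp than in CK and 207 higher. In TaFp against Fp, 1248 of the 2210 were at least 2-fold higher and 17 at least 2-fold lower. At a mean FPKM of at least 5 the class held 1278 genes, with 382 lower and 39 higher in TaFp than in CK, and 792 higher than in Fp. With voom it held 3172, with 938 and 173, and 2242 higher than in Fp and 39 lower. With a pseudocount of 0.1 it held 3062, with 883 and 153, and 2143 higher than in Fp and 41 lower. The 48 became 83 with a pseudocount of 0.5 and 78 with TPM rescaling.

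A further group of genes was highest with both strains. In TaFp, 1020 genes were at least 2-fold higher than in each of CK, Ta and Fp, and 140 were at least 2-fold lower than in each. The first number was 471 at a mean FPKM of at least 5 and 1511 with voom. The second was 124 at that filter, 220 after quantile normalization, 300 with a pseudocount of 0.1 and 306 with voom. The ratio of the 2 numbers thus depends on the settings. The 1020 genes had a median log2 fold change of 1.8 in TaFp against CK, and of -0.16 in Ta and 0.22 in Fp. Of these genes, 34 were also at least 2-fold higher in Ta than in CK, and 186 in Fp. At least 2-fold lower than in CK were 133 in Ta and 58 in Fp. MD04G1031500, MD04G1031400 and MD11G1238600 are among genes of this kind, at 188, 249 and 199 FPKM in TaFp.

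**Figure D3:**
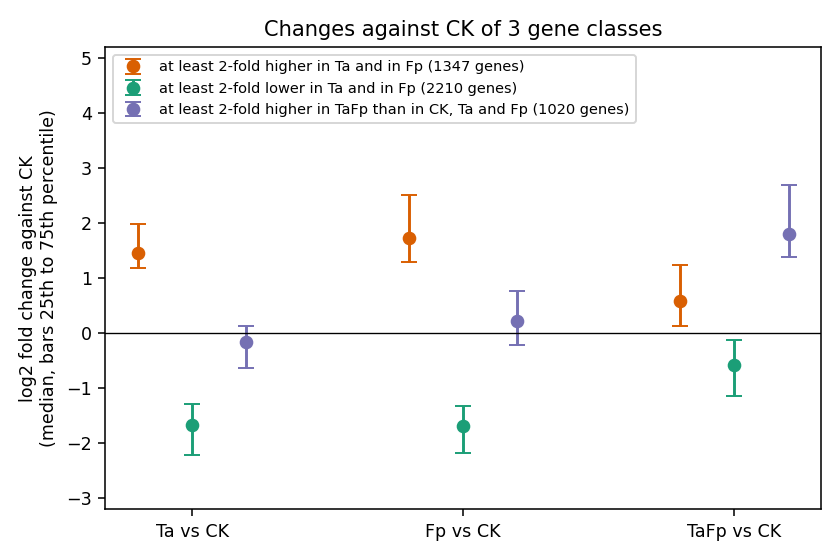
Median log2 fold change against CK, with bars from the 25th to the 75th percentile, in Ta, Fp and TaFp for 3 classes of genes chosen by their calls of at least 2-fold. Genes higher in both Ta and Fp have medians of 1.46, 1.73 and 0.58, and genes lower in both have medians of -1.67, -1.68 and -0.57.

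The interaction tests whether the change with 6S-2 differed between roots with and without MR5, relative to effects that add on the log2 scale. It was called for 22781 genes, with 13023 higher and 9758 lower, and for 11775 at a difference of at least 2-fold, with 7321 higher and 4454 lower. MD14G1158400 and MD15G1255700 had the largest rises, at 11.27 and 10.73 on the log2 scale, and both fell with either strain alone and less with both, to 111 ± 2.7 and 30.6 ± 0.77 FPKM in TaFp. MD09G1256000 and MD10G1022900 had the largest falls, at -13.16 and -12.19. Both rose with either strain alone and stood at 9.17 ± 0.69 and 2.73 ± 0.43 FPKM in TaFp (SD, n = 3 each). Their limma adjusted p were 7.74e-19, 7.65e-17, 4.76e-18 and 1.93e-17.

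The share of higher genes among the 22781 was 57.2%, and 47.2% after quantile normalization and 44.4% with the length trend removed. Among genes changed at least 2-fold it was 62.2%, and 72.3% after TPM rescaling, 50.1% after quantile normalization and 51.3% with the length trend removed.

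The change with strain treatment also varied with gene length. In the eighth of tested genes with the longest length, from 2787 bp, the median log2 fold change was -0.303 in Ta, -0.517 in Fp and -0.048 in TaFp against CK. In the next-to-shortest eighth, from 660 to 957 bp, it was 0.149, 0.151 and 0.012, and in the shortest it was 0.02, -0.08 and -0.019, so it did not fall steadily with length. Length accounted for 2.5%, 4.7% and 0.2% of the variance of the log2 fold changes in these comparisons.

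**Figure D4:**
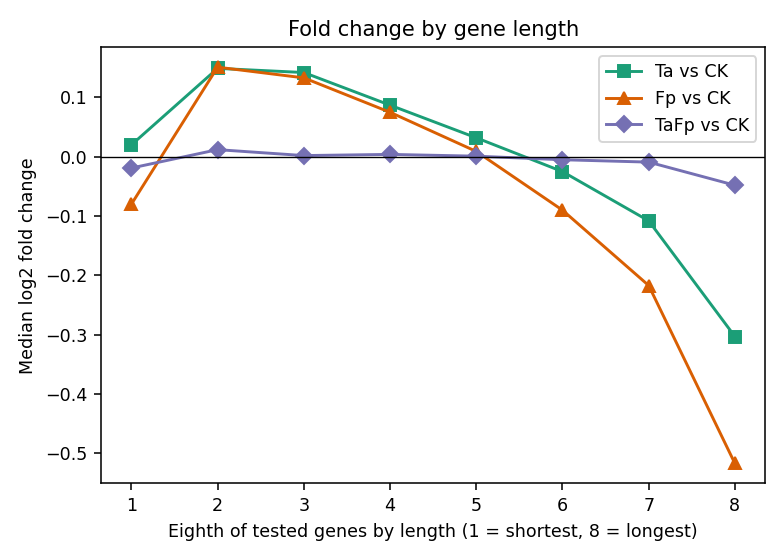
Median log2 fold change against CK in each eighth of the 30459 tested genes by length, from 1 (shortest) to 8 (longest), with a line for each of Ta, Fp and TaFp. The lines of Ta and Fp end at -0.303 and -0.517 in the longest eighth, and that of TaFp at -0.048.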

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

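The interaction was planned before the data were examined, and the permutation around additive effects was set before its result was seen. The other tests in this part were chosen after the results were seen. The change with 6S-2 differed between roots with and without MR5 in 22781 genes, by the interaction term of the limma fit. Genes that reach the same level under either strain and under both also show such a difference, since the term is set against effects that add on the log2 scale. Of the 22781 genes, 13718 were called in opposite directions in Ta against CK and in TaFp against Fp. For MR5, 11010 were called in opposite directions in Fp against CK and in TaFp against Ta. On the scaling of the main fit, an equal level under 1 strain and both is argued against for these genes. It stays open for the others. All 14 named genes had a called interaction, as did 74.8% of all tested genes. The named genes were picked for large changes, so their calls are no separate result. The interaction was -13.16 for MD09G1256000, -12.19 for MD10G1022900, -12.13 for MD09G1256300, -10.92 for MD13G1208400 and -5.35 for MD15G1176400 on the log2 scale. It was 11.27 for MD14G1158400, 10.73 for MD15G1255700, 9.27 for MD04G1031500, 9.21 for MD05G1255500, 7.17 for MD04G1031400, 5.6 for MD11G1238600 and 5.23 for MD07G1278100. It was small for MD02G1023200, at -0.7, and for MD03G1011800, at 0.5.

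Other groupings of the libraries were tried for each count. For the interaction, 1 of 100 assignments of the 12 libraries to groups of 3, the real one, gave as many genes, and the highest of the others gave 5082. This excludes chance only for libraries with no difference between any groups, and does not bear on the interaction alone. For the interaction alone, residuals of a fit with additive effects of 6S-2 and MR5 were permuted over the libraries. The real table was the only 1 of 100 to give 22781 genes or more, and the highest other gave 10933, so chance residuals around additive effects are argued against. Neither test addresses chance between plants, since the libraries may not come from separate plants. The real counts of 20088, 22146, 20627, 20989 and 17578 genes in the 5 comparisons of 2 groups stood against a highest other count of 0, with 1 of 10 splits, the real one, as large in each. With 10 splits the share cannot go under 0.05.

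The changes with 6S-2 alone and MR5 alone were alike and were mostly smaller when both were given. Noise between the shared CK libraries is argued against as the whole source, since the covariance exceeded the simulated one by 0.6584. The highest of 100 simulated covariances was 0.0099. The simulation drew on the spread within groups, so it cannot address a CK group that differed as a whole. Splitting the controls cannot address this either, since all came from the same CK group. A trend with gene length is argued against as the whole source, since r was 0.823 after its removal. An unlabelled difference in handling or batch that set CK and TaFp apart from Ta and Fp cannot be told apart from the treatments, because such a difference would coincide with the groups and the labels give no batch. The first component, with 53% of the variance, follows that grouping, but it restates the pattern and lends no weight to either. The treatments themselves stay among the open explanations, as untested.

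Long genes were lower in Ta and Fp than in CK. In Fp against CK the longest eighth of genes lay below the middle eighths in all 4 bins of mean expression, by gaps from -0.181 to -0.74. A length-dependent loss in the RNA or the library preparation and a true change in the expression of long genes both give such gaps, so these cannot be told apart here. A few abundant genes taking more of the reads would shift all other genes by 1 factor, and this is argued against by a gap of -0.512 between the longest and the middle eighths.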

How the results depend on the processing

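Tests of gene length, voom, split controls, gene classes and the counts of at least 2-fold under other settings were added after seeing the data. So was leaving out each library for the correlations. Of the alternatives, 476 were run on named genes and all kept the direction and the call, with a largest adjusted p of 1.01e-08. The named genes were picked for the largest changes, so this does not speak for typical calls. Requiring a 2-fold change as well lowered the counts to 4920 (Ta against CK), 6466 (Fp against CK), 4835 (TaFp against Fp), 5698 (TaFp against Ta), 3781 (TaFp against CK) and 11775 (interaction), by construction. Counts of at least 2-fold at a mean FPKM of at least 5, where fewer genes are tested, were 3226, 4222, 2867, 3408, 2144 and 7443 in that order. The other 291 values for counts and correlations stayed within 1.5 times (counts) or within a spread of 0.007, 0.012 and 0.008 (correlations, in the order below), which is the standard deviation of the leave-one-out values scaled up for 12 libraries. The limit for counts is wide. Within it, counts of at least 2-fold rose with voom to 7231, 9160, 7154, 8018, 5403 and 13813, in the order of the contrasts above. A pseudocount of 0.1 gave 7020, 8948, 6965, 7843, 5246 and 13733. The correlation of the 6S-2 changes with and without MR5 was -0.612 with a pseudocount of 0.1, -0.679 at a mean FPKM of at least 5, -0.62 with the length trend removed and -0.609 with voom. That of the MR5 changes was -0.314 at a mean FPKM of at least 5 and -0.275 with the length trend removed. That of 6S-2 and MR5 was 0.814 with a pseudocount of 0.1, 0.838 at a mean FPKM of at least 5, 0.811 with voom and 0.798 with no shared control. Leaving out 1 library gave -0.633 to -0.624, -0.296 to -0.282 and 0.821 to 0.829. The cause of these shifts was not tested. Genes higher in both Ta and Fp numbered 2029 with a pseudocount of 0.1 and 2097 with voom (1347 in the main fit), genes lower in both 1278 at a mean FPKM of at least 5 (2210), genes highest in TaFp 471 at that filter (1020), and genes lowest in TaFp 300 with a pseudocount of 0.1, 220 after quantile normalization and 306 with voom (140). The replicate numbers did not pair the samples, with deviations of same-numbered libraries correlating at -0.078 to 0.019, and a replicate block gave 19914, 21999, 20407, 20834, 17363 and 22651 genes. The gene lists could not be run without descriptions. In the simulation, 6% of planted 1.2-fold changes were found. Few genes were changed there, which makes the adjusted p stricter than in the real data. The 6% is therefore no estimate of the share missed here.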

Other observations

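Some changes were close to on and off. At least 100 reads in every CK library and at most 3 in every Fp library were seen in 23 genes, and 10 genes showed the opposite. For TaFp, 20 genes had at least 100 reads in every library and at most 3 in every Ta library, and 19 did so against CK. Only 5 genes held at least 100 reads in CK and at most 3 in TaFp, against 41 for Ta. Some 606 genes were at least 2-fold higher in Fp and in TaFp and not called at that size in Ta, and 35 were higher in Ta and in TaFp and not called in Fp. The matching counts of lower genes were 216 and 83. With voom the 606 became 910 and the 35 became 72, and the 35 became 18 with the length trend removed.

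Among the genes with the most reads, chosen after their values were seen, MD11G1109200 fell from 9207 ± 904 FPKM in CK to 1389 ± 86.4 in Ta and 2182 ± 49.8 in Fp, and stood at 5791 ± 189 in TaFp (SD, n = 3 each). MD12G1141500 rose from 4561 ± 153 to 9506 ± 366 in Ta and 10710 ± 243 in Fp, and stood at 5018 ± 49.1 in TaFp. MD04G1128900 followed MR5 instead, at 2339 ± 21.7 in CK, 2596 ± 132 in Ta, 4999 ± 236 in Fp and 5980 ± 317 in TaFp, and its interaction was not called (limma adjusted p = 0.17).

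Genes with neighbouring identifiers changed in the same direction more often than chance; of the tests here, only that on neighbours of unlike length was set before its result was seen. In Fp against CK, 1203 of 30441 neighbouring pairs shared a call of at least 2-fold in one direction, against a mean of 699 and a highest of 755 in 100 permutations within chromosomes. Over the 5 comparisons the lowest ratio to the permuted mean was 1.6. Reads shared between tandem copies of like length are argued against as the whole source, since pairs whose lengths differ by more than 1.5 times also exceeded the permutations in all 5 comparisons, at 1.4 times the permuted mean or more. Copies of unlike length that share reads, and shared regulation, both stay open, and no biological explanation was tested.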
